A study of Populus ussuriensis with 9 samples.

How the data were processed

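RNA-seq libraries were made from fully expanded leaves of Populus ussuriensis, a poplar tree, and the values came as 1 table with a column for each of 9 libraries. The plants were wild type (WT) or belonged to 1 of 2 transgenic lines that overexpress LbDREB6, the line OE14 at a moderate level and the line OE18 at a high level, per the labels. Each group had 3 libraries, which the series describes as biological replicates. Leaf RNA was isolated by a CTAB method and made into Illumina libraries, per the labels' protocols. The 6 columns of the transgenic lines carry the sample titles. The other 3 columns are headed with C and a number, and were taken as the WT libraries by elimination. Plants were 6 months old and had water withheld. The sample descriptions give 2 weeks of drought and the treatment protocol gives 1 week without water, and the difference could not be settled. No watered plants were analysed here, so every comparison is between genotypes under drought.

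The values are FPKM, fragments scaled to gene length in kilobases and to the reads assigned in the library, as deposited by the authors for 29764 locus IDs. The submitters' processing notes name Bowtie2 2.2.3 and HISAT2 2.1.0. The counting tool, the genome build and the annotation release are not given in the sources used here, and nor is whether the counting used strand or how it treated reads shared between similar genes. The IDs were used as the table gives them. The table does not pair them with gene names, and no annotation was used here, so no gene function is stated and at most 2 IDs that rose and 2 that fell are printed. For the same reason 32 gene lists that had been fixed by gene description could not be applied. LbDREB6 itself was not analysed here, so the overexpression was not checked in these libraries. The chromosome of a gene was read from its ID, in which the digits before the G give the chromosome and a T marks a locus that is not placed on one. Positions and neighbours therefore follow the order of the IDs. Whether the genome of these Populus ussuriensis plants has the same order was not examined.

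The depth of each library was recovered from the values. FPKM is a whole number of reads divided by the gene's length and the library's total, so ratios of low values within a gene give the totals. All 29764 genes gave whole reads within 1e-06 reads. This is met by construction for 759 genes above 0 in a single library. Of the 29005 genes above 0 in 2 or more libraries, 28929 also gave a gene length that was a whole number of bases within 1e-05, and the other 76 did so only after their reads were multiplied by a common factor. In data simulated with known reads, 99.83% of the genes came out exact and the totals had an error of 0 reads. The recovered totals ran from 10988010 to 16221919 reads per library. At 1 kilobase, 3 reads correspond to an FPKM of 0.185 in the deepest library and 0.273 in the shallowest. The upper limit for a gene without reads was set at 3 reads over the 3 libraries of its group. Such limits cover counting error only, since the reads carry no molecular identifiers as far as the labels say.

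Genes with an FPKM of 1 or more in at least 3 of the 9 libraries were tested, which left 22848. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a trend in the variance prior, in 1 fit over all 9 libraries with 6 residual degrees of freedom. The contrasts were OE14 against WT, OE18 against WT, OE18 against OE14, and the mean of both lines against WT. A moderated F test compared the 3 groups. All limma tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. In data simulated for OE14 against WT over 22345 tested genes, limma called 22% of the genes changed by 1.25-fold, 62% of those changed by 1.5-fold, 88% of those changed by 2-fold and 100% of those changed by 4-fold. Each size had 50 genes. In that simulation 3.55% of the calls were unchanged genes. Only these few genes were changed, and every gene had the same spread beyond counting, 4.85%. A far larger share of the genes was called in the real comparison, which makes the adjusted p threshold less strict there. The simulated shares need therefore not hold for the real libraries.

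Overlap between the comparisons with WT was set beside 20 simulations of unchanged groups, and beside the overlap of independent lists. In these simulations the WT libraries were simulated too, and both comparisons shared them. The noise had each gene's residual spread and was drawn independently for each gene. The 3 WT libraries were too few to be divided between the lines. For values along chromosomes, the log2 ratio of group mean FPKM was taken for 15044 genes with a mean FPKM of 5 or more, with values under 0.01 set to 0.01. Medians were taken in windows of 50 neighbouring genes, and the most extreme window was compared with 1000 permutations of blocks of 10 genes. These permutation p-values are one-sided, taken separately for the highest and the lowest window. Intervals of a median over genes are 95% bootstrap intervals from 2000 draws. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

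The rule for named genes, the limma contrasts, the F test, the overlap of the lines, the gene lists and the main list of alternatives were set before the data were examined. Values along chromosomes with their permutation p-values and bootstrap intervals were not in that plan. Nor were the deciles of gene length and abundance or the counts of genes without a read. For genes without descriptions the rule allowed at most 2 that rose and 2 that fell. The genes taken were those with the largest rise and the largest fall in OE14 against WT and in OE18 against WT, among called genes whose libraries did not overlap between the groups and whose higher group mean was 5 FPKM or more. A gene chosen after its values were seen is marked as such. The alternatives were other pseudocounts, filters, scalings, thresholds, variance models and library weights, a term for the replicate number, fits with only the compared groups, and each library left out in turn. A fit with limma voom on the recovered reads, a fit without the gene with the highest mean FPKM, a fit without 2 chromosome stretches, and the counts at thresholds of 2-fold and 4-fold under each alternative were added after the data were seen.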

Results

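Transcript levels were measured by RNA-seq in fully expanded leaves of drought-treated Populus ussuriensis plants of 3 genotypes, with 3 libraries each. The genotypes were WT, the line OE14 with moderate overexpression of LbDREB6, and the line OE18 with high overexpression. The name DREB stands for dehydration-responsive element binding, a family of plant transcription factors. Library depth was 13389816, 11598968 and 11324024 reads in WT, 11707298, 16221919 and 14834985 in OE14, and 13441298, 13653249 and 10988010 in OE18. Each level of overexpression was represented by a single line, so level and line cannot be separated.

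The 3 genotypes formed 3 separate groups of libraries. Pearson's r of log2(FPKM + 1) across genes was 0.991 to 0.994 between libraries of the same genotype. It was 0.950 to 0.952 between WT and OE14, 0.806 to 0.813 between OE14 and OE18, and 0.772 to 0.779 between WT and OE18. The first principal component held 81.5% of the variance and set OE18 apart, and the second held 13.8% and separated OE14 from WT. Libraries of the same genotype differed by more than sampling noise, with a median chi-square of 1.59 to 2.17 times the chance value. Among genes with a mean of 100 reads or more, the coefficient of variation beyond counting was 4.16% in WT, 4.93% in OE14 and 5.45% in OE18. Each library was counted as a separate replicate, as the series describes them. The spread by itself does not show that they came from separate plants, and the limma p-values rest on this spread. More genes reached an FPKM of 1 in the transgenic lines. The number of genes at an FPKM of 1 or more was 20572 ± 9.24 (SD, n = 3) in WT, 21028 ± 81.5 (SD, n = 3) in OE14 and 21974 ± 57.0 (SD, n = 3) in OE18, with no overlap between the libraries of the groups. The FPKM values of a library also summed to more in OE18 (553425 to 563135) than in WT (521892 to 525406) or OE14 (524619 to 530746). The count was not repeated after rescaling. The smallest two-sided p that an exact permutation test of 3 libraries against 3 can give is 0.1, so single measures of this kind were not tested.

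**Figure D1:**
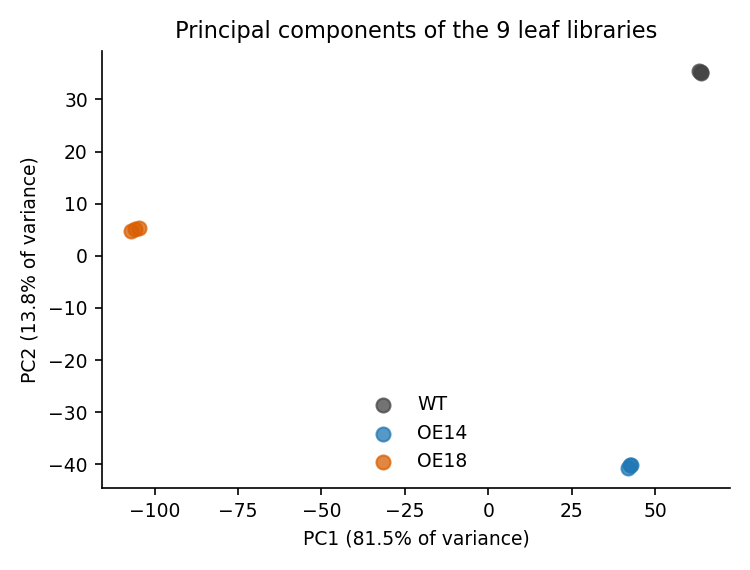
Principal components of log2(FPKM + 1) of the 22848 tested genes, with 1 point per library, coloured by genotype. The axes give the component scores; the first component (81.5% of the variance) sets the 3 OE18 libraries apart and the second (13.8%) separates OE14 from WT.

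The first comparison asked how leaf transcription differed between OE14 and WT under drought. Most differences were small. In OE14, 812 genes were higher and 441 lower than in WT by 2-fold or more, which is 5.48% of the genes tested. At 4-fold or more, 45 genes were higher and 107 lower. These numbers depend on how low values are treated. With a pseudocount of 0.1, 1788 genes were higher and 774 lower by 2-fold or more and 243 and 191 by 4-fold or more, and limma voom on the recovered reads gave 1885 and 834, and 384 and 224. Falls outnumbered rises at 4-fold with a pseudocount of 0.5 (78 higher, 133 lower) and among genes of a mean of 5 FPKM or more (39 higher, 85 lower), but not with a pseudocount of 0.1 or with voom. The largest rise was that of Potri.006G234900.v3.0, from 2.06 ± 0.32 FPKM in WT to 27.7 ± 3.7 in OE14 (SD, n = 3 each), a log2 fold change of 3.23 (SE 0.15, limma adjusted p = 6.5e-10). The largest fall was that of Potri.T020000.v3.0, which had 64.9 ± 1.7 FPKM in WT and not a single read in the 3 OE14 libraries (SD, n = 3 each; limma adjusted p = 5.5e-16). With 3 reads over the group as the upper limit, it was at least 735-fold lower in OE14.

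Without a size threshold, limma called 12074 genes in OE14 against WT, 52.8% of those tested, with a median absolute log2 fold change of 0.46. Of these, 7297 were higher and 4777 lower. The libraries of OE14 and WT did not overlap in 60.4% of the tested genes, where chance gives 10%. Calls were more frequent among abundant genes, from 34.6% of the lowest decile by mean FPKM to 76.3% of the highest. Quantile normalization, which gives every library the same distribution, divided the calls into 5883 higher and 5787 lower, and those of 2-fold or more into 591 and 502. Median-of-ratios scaling, which divides each library by the median of its gene ratios, gave 6225 and 5861, and 687 and 504. Rescaling each library to the same sum gave 7212 and 4832, and 1096 and 571. The excess of higher genes was therefore smaller under the first 2 of these scalings.

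**Figure D2:**
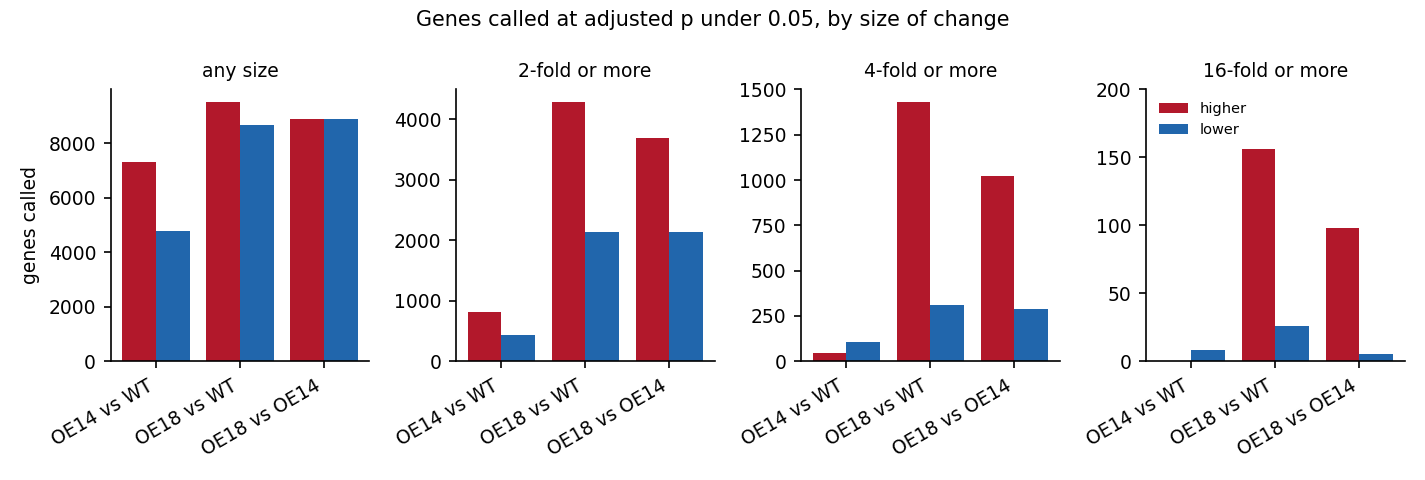
Numbers of genes called by limma at an adjusted p under 0.05 in the 3 comparisons, as bars for genes higher (red) and lower (blue) in the genotype named first, for changes of any size and of at least 2-fold, 4-fold and 16-fold on the log2(FPKM + 1) scale. Each panel has its own linear axis from 0; at 4-fold or more OE14 had 45 genes higher and 107 lower than WT, and OE18 had 1431 higher and 309 lower.

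In 2 stretches of neighbouring loci, which were singled out after their values were seen, most genes differed between OE14 and WT in the same direction. At the start of chromosome 5, the 160 genes with a mean FPKM of 5 or more and locus numbers from 100 to 63300 had a median log2 ratio of -0.75 (95% bootstrap interval over genes -0.86 to -0.70), against 0.06 for genes elsewhere. Of these genes, 90.6% lay below the median elsewhere. At the start of chromosome 18, the 100 genes with locus numbers from 100 to 24700 had a median of 0.48 (interval 0.42 to 0.56), and 95% lay above the median elsewhere. Every OE14 library showed both shifts. Relative to genes elsewhere, the chromosome 5 stretch lay at -0.88, -0.81 and -0.84 in the 3 OE14 libraries and between -0.01 and 0.01 in the WT libraries, each set against the other WT libraries. The chromosome 18 stretch lay at 0.44, 0.42 and 0.42 in OE14 and between -0.03 and 0.01 in WT. Among all tested genes of these stretches, 210 of 297 on chromosome 5 were called lower in OE14 (70.7%, against 20.3% elsewhere) and 98 of 141 on chromosome 18 were called higher (69.5%, against 31.7% elsewhere). The chromosome 5 stretch held 44 of the 441 genes that were lower by 2-fold or more. Over all windows of 50 neighbouring genes, the lowest median in OE14 against WT was on chromosome 5 (-0.93 relative to all genes, permutation p = 0.001, the smallest that 1000 permutations can give) and the highest on chromosome 18 (0.48, permutation p = 0.003). In OE18 against WT the highest window, on chromosome 13, had a permutation p of 0.81 and the lowest, on chromosome 2, one of 0.96.

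**Figure D3:**
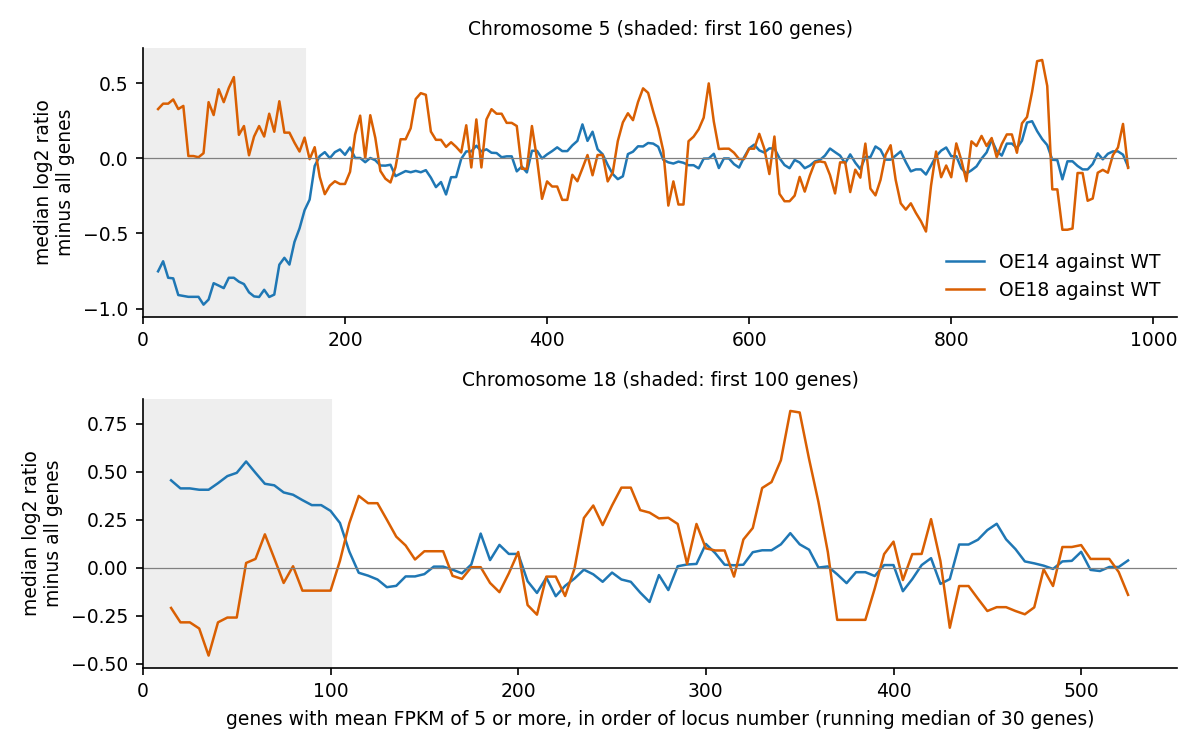
Running median over 30 genes of the log2 ratio of mean FPKM, minus the median of all genes, along chromosomes 5 and 18 in order of locus number, for OE14 against WT (blue) and OE18 against WT (orange). In OE14 the running median lies below 0 over the first 160 genes of chromosome 5 and above 0 over the first 100 genes of chromosome 18 (shaded), whose medians are -0.75 and 0.48 before the median of all genes is taken off.

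The second comparison asked the same of OE18, the line with high overexpression. Differences were more numerous and larger, and large changes were mostly rises. By 2-fold or more, 4290 genes were higher and 2132 lower in OE18 than in WT, 28.1% of the genes tested. At 4-fold or more 1431 genes were higher and 309 lower. With a pseudocount of 0.1 the genes of 4-fold or more were 2452 higher and 643 lower, and with voom 2556 and 686. With genes of a mean of 5 FPKM or more only, 2397 were higher and 1692 lower by 2-fold or more, and 876 and 271 by 4-fold or more. Genes without a read in WT contributed to the rises: 101 genes that had no read in the 3 WT libraries reached a mean of 1 FPKM or more in OE18, 17 of them 5 FPKM or more, while 27 genes at a mean of 1 FPKM or more in WT had no read in OE18. The largest rise was that of Potri.006G256100.v3.0, from 0.521 ± 0.14 FPKM in WT to 372 ± 20 in OE18 (SD, n = 3 each), a log2 fold change of 7.94 (SE 0.11, limma adjusted p = 5.7e-16). The WT value rests on 13 reads over the 3 libraries. The largest fall was that of Potri.012G022400.v3.0, from 1020 ± 60 to 13.6 ± 0.62 FPKM (SD, n = 3 each), a log2 fold change of -6.12 (SE 0.051, limma adjusted p = 1.5e-17).

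Without a size threshold, limma called 18158 genes in OE18 against WT, 79.5% of those tested, 9510 of them higher and 8648 lower. The libraries of the 2 genotypes did not overlap in 80.3% of the genes, where chance gives 10%. The longest genes lay lower in OE18 than the others. The median log2 fold change was -0.34 in the decile of the longest genes (median length 4055 bases) and highest, at 0.26, in the decile with a median length of 1059 bases. The decile of the shortest genes (719 bases) had 0.05, so the relation was not monotonic, with a Spearman's rho of -0.12 across genes. In OE14 against WT the medians of these 3 deciles were -0.02, 0.07 and 0.04. Quantile normalization moved the median of all genes from 0.03 to -0.15 in OE18 against WT and from -0.01 to -0.12 in OE18 against OE14. In OE18 against WT, under that scaling, 8028 genes were called higher and 10647 lower, and the genes of 2-fold or more were divided into 3458 and 3204, and those of 4-fold or more into 1143 and 446, so the direction of small changes and the size of the excess of rises rest on the scaling.

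The third comparison set the line with high overexpression directly against the line with moderate overexpression. By 2-fold or more, 3690 genes were higher and 2146 lower in OE18 than in OE14, and by 4-fold or more 1024 were higher and 288 lower. After quantile normalization the genes of 2-fold or more were 3236 higher and 2813 lower. With genes of a mean of 5 FPKM or more only they were 2162 and 1683. At 4-fold or more a pseudocount of 0.1 gave 1815 higher and 635 lower, and voom 1913 and 675. The 4 named genes followed different courses over WT, OE14 and OE18. Potri.012G022400.v3.0 fell in both steps, with 141 ± 4.8 FPKM in OE14 (SD, n = 3) between the WT and OE18 levels, a log2 fold change of -2.84 from WT to OE14 and of -3.29 from OE14 to OE18 (limma adjusted p = 5.3e-14 and 5.7e-15). Potri.006G256100.v3.0 rose in both steps, with 5.87 ± 1.2 FPKM in OE14 (SD, n = 3) and log2 fold changes of 2.16 and 5.77 (limma adjusted p = 1.8e-09 and 2.6e-14). Potri.T020000.v3.0, without a read in OE14, had 111 ± 9.6 FPKM in OE18 (SD, n = 3), above WT by 0.76 on the log2 scale (limma adjusted p = 1.2e-07). Potri.006G234900.v3.0, which rose in OE14, had 1.58 ± 0.54 FPKM in OE18 (SD, n = 3), a log2 fold change from WT of -0.26 that limma did not call (adjusted p = 0.11). Without OE18 replicate 2 that change was -0.42 and was called (limma adjusted p = 0.012), as it was after rescaling each library to the same sum (TPM; -0.39, adjusted p = 0.049) and after quantile normalization (-0.64, adjusted p = 0.001).

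**Figure D4:**
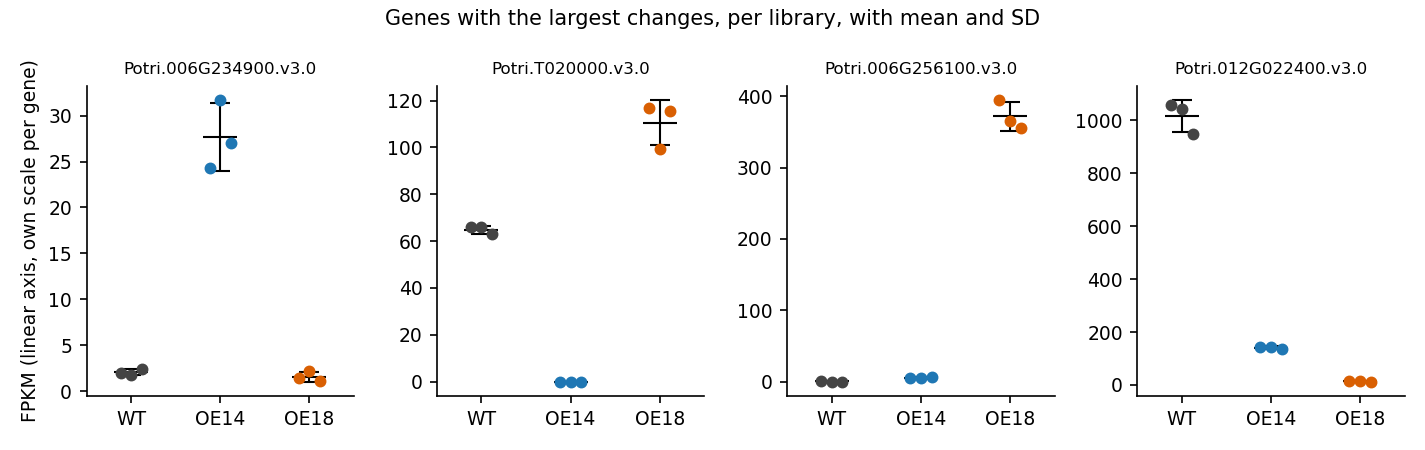
FPKM of the 4 named genes in each library, with 1 point per library and the mean with SD of the 3 libraries of each genotype in black. Each panel has its own linear axis; Potri.012G022400.v3.0 falls from WT over OE14 to OE18, Potri.006G256100.v3.0 is high in OE18 (372 FPKM), Potri.006G234900.v3.0 is high in OE14 (27.7 FPKM) and Potri.T020000.v3.0 is at 0 in OE14.

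Without a size threshold, limma called 17745 genes in OE18 against OE14, 8869 higher and 8876 lower, or 7949 higher and 10213 lower after quantile normalization. The libraries did not overlap in 79.1% of the genes, where chance gives 10%. Genes called both from WT to OE14 and from OE14 to OE18 took all 4 combinations of direction. There were 2861 genes that rose in both steps, 1609 that fell in both, 3232 that rose and then fell, and 2171 that fell and then rose. Independent lists of the same sizes would share 2833, 1856, 2835 and 1854 genes, and the steps share the OE14 libraries, which by itself favours opposite directions.

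The design also asks which changes the 2 lines had in common. Of 10144 genes called against WT in both lines, 7063 (69.6%) changed in the same direction, 4300 higher and 2763 lower in both. The remaining 3081 genes changed in opposite directions, and all 3081 were also called in OE18 against OE14. Changes were larger in OE18: among genes that changed in the same direction, the median ratio of the OE18 to the OE14 log2 fold change was 1.84, and 78.5% had the larger change in OE18. The direct test called 4470 of the 7063 genes as changed more strongly in OE18 and 713 as changed more strongly in OE14, and it did not call 1880. Independent lists of the same sizes would share 3037 genes that were higher and 1808 that were lower. Both comparisons use the same WT libraries. Across genes, which are not independent replicates, the log2 fold changes of the lines had a Pearson's r of 0.42 and a Spearman's rho of 0.37. The same sign was found in 62.7% of all tested genes. Unchanged groups, simulated together with the WT libraries that they shared, gave an r of 0.50 and the same sign in 66.6%. Equal groups that share a control give about these values from noise alone, so the 2 values are no yardstick for how alike the lines are. The covariance of the log2 fold changes was 0.243 against 0.006 in the unchanged groups, a difference of 0.237. For the unchanged groups limma called 0 genes in common. Noise of the simulated size in shared WT libraries, independent from gene to gene, would therefore account for little of the covariance. Noise common to many genes was not simulated. A difference of the WT libraries as a whole would still enter both comparisons, and they were too few to be divided. Quantile normalization gave 3173 genes higher and 3678 lower in both lines.

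**Figure D5:**
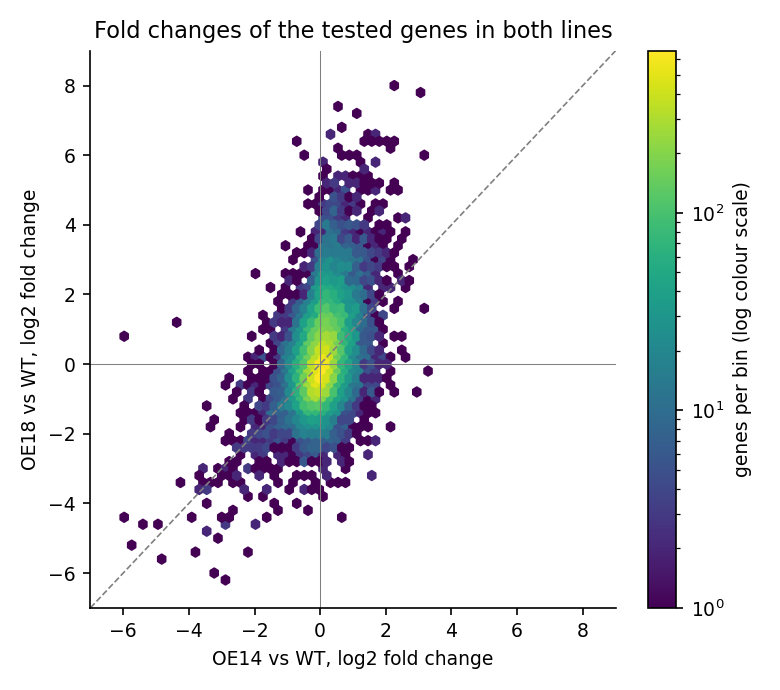
Log2 fold change against WT of each of the 22848 tested genes in OE14 (horizontal axis) and OE18 (vertical axis), as hexagonal bins coloured by the number of genes on a log scale; the dashed line marks equal change. The cloud extends further along the OE18 axis, and its Pearson's r across genes is 0.42.

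With both lines averaged and set against WT, limma called 16253 genes, 9065 higher and 7188 lower, and 7396 higher and 9224 lower after quantile normalization. The moderated F test called 20088 genes, 87.9% of those tested, as different among the 3 genotypes.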

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

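The tests of the shared response and of copy number were chosen only after the results were seen; the test of gene length and the counts over other splits of the libraries were set before theirs were.

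The 2 lines differed from each other in more genes than OE14 differed from WT. The direct test of OE18 against OE14 called 17745 genes, and 3081 genes were called against WT in opposite directions in the lines. All 4 named genes differed between the lines by this test. The log2 fold change of OE18 against OE14 was -3.49 for Potri.006G234900.v3.0, 6.80 for Potri.T020000.v3.0, 5.77 for Potri.006G256100.v3.0 and -3.29 for Potri.012G022400.v3.0. The value of Potri.T020000.v3.0 depends on the pseudocount, since it had no read in OE14. With 3 reads over the group as the upper limit, it was at least 1253-fold higher in OE18.

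The start of chromosome 5 and the start of chromosome 18 also differed between the lines. In OE18 against OE14 the chromosome 5 stretch lay 1.15 above genes elsewhere and the chromosome 18 stretch lay at -0.62 relative to genes elsewhere, on the log2 scale. All 3 OE14 libraries shifted one way from WT and all 3 OE18 libraries the other way in both stretches. The OE18 shifts were not shown to be regional. In that line no window of 50 genes stood out from permuted blocks, with most extreme medians of 0.56 and -0.44 (permutation p = 0.81 and 0.96). A test between libraries was not made for the difference between the lines.

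For the shifts of these stretches in OE14, gene length is argued against, because genes elsewhere matched to them in length had median log2 ratios of 0.07 for chromosome 5 and 0.05 for chromosome 18. A response of these loci to the transgene that both lines share is argued against as well, since in OE18 against WT the stretches shifted the other way, by 0.32 and -0.15. The loss of 1 of 2 copies in every cell with reads in proportion would give -1, outside the intervals around the shift of -0.81 (-0.92 to -0.76) and around that of the first 120 genes (-0.84, -0.95 to -0.78), though the edge of the stretch was chosen from the same values and running medians of 30 genes reached -0.97; 1 copy gained over 2 would give 0.58 on chromosome 18, and this stays open, since the shift was 0.42 (0.36 to 0.50) over the stretch but 0.49 (0.39 to 0.58) over its first 75 genes. A copy number change specific to OE14 may account for both stretches. The genes shifted as a body, with interquartile ranges 1.04 and 0.91 times those elsewhere, as such a change would need. A regional change in regulation that moved the genes alike would give such ratios too, and the edges were chosen from the same values. The ratios therefore do not decide between these explanations. No DNA was analysed here, and a regional change in regulation in OE14 stays open and was not tested.

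Other splits of the libraries bear on the counts of called genes. For each pair of genotypes, 1 of the 10 possible splits of the 6 libraries is the real one, which is too few for a share under 0.05. The real splits gave 12074 genes in OE14 against WT, 18158 in OE18 against WT and 17745 in OE18 against OE14, and the most that limma called in another split was 0 in each. At an unadjusted p under 0.05 the other splits gave at most 570, 171 and 207 genes. For the mean of both lines against WT, 2 of 100 splits of the 9 libraries gave as many genes as the real 16253. This share is under 0.05, and only in that sense can chance be excluded for the count. The highest of the others was 18505, from the same 3 groups of libraries with the genotype names exchanged. A split that parted a genotype still gave 15517. Both values point to the distance of OE18 from the rest, so the split count does not bear on a difference from WT that both lines share. For the moderated F test 1 of 88 splits, the real one, gave as many as 20088, and the highest of the others gave 14006. Chance can be excluded only in the sense that the libraries group by their genotype label. The split count does not bear on what made the groups differ. For genes changed in the same direction in both lines, 3 of 100 splits gave as many as the real 7063, a share under 0.05. Chance can be excluded in that sense only, because the highest of the others was 14844, again from the 3 groups with names exchanged, and 13131 came from a split that parted a genotype. These larger counts point to a structure of the libraries, the distance of OE18 and the control shared by both comparisons, so the split count does not bear on a response common to both lines.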

How the results depend on the processing

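The fits with voom, without the gene with the highest mean FPKM and without the 2 chromosome stretches, all counts at 4-fold or more, and the counts at 2-fold or more under a further alternative were chosen after seeing the data; the threshold of 2-fold by itself was set before. Of 285 counts of called genes under an alternative, 268 lay within 1.5 times the main count. The others are given here. Asking for a change of 2-fold or more as well, a stricter threshold, reduced the calls to 1253 in OE14 against WT, 6422 in OE18 against WT, 5836 in OE18 against OE14, 2876 for the mean of both lines, 6904 for the moderated F test and 720 in the same direction in both lines. For genes of 2-fold or more in OE14 against WT, a pseudocount of 0.1, which shrinks low genes less, gave 2562, and voom on the recovered reads gave 2719. A filter at a mean of 5 FPKM, which tests fewer genes, gave 4089 genes of 2-fold or more in OE18 against WT, 3845 in OE18 against OE14 and 1147 of 4-fold or more in OE18 against WT. Genes of 4-fold or more numbered 434 with a pseudocount of 0.1 and 608 with voom in OE14 against WT (152 in the main analysis), 3095 and 3242 in OE18 against WT (1740), and 2450 and 2588 in OE18 against OE14 (1312). Voom changes the offset, the scale and the weights together, and the cause of its differences was not tested. With each library left out in turn, the calls ranged from 10852 to 12260 in OE14 against WT, from 17524 to 18149 in OE18 against WT, from 16990 to 17719 in OE18 against OE14, from 15227 to 16108 for the mean of both lines, from 19672 to 19817 for the F test and from 6360 to 7005 in the same direction in both. At 2-fold or more the ranges were 1249 to 1274, 6391 to 6503 and 5828 to 5908 for the comparisons of pairs, and at 4-fold or more 151 to 155, 1729 to 1783 and 1312 to 1345. The deviations of same-numbered libraries from their group means correlated at -0.02 to 0.10 and those of others at -0.12 to 0.07, and 6 of 9 libraries correlated best with their own number, a hint from the data at most, so the numbers were not taken to pair the libraries. With a replicate block the calls were 12252, 18223, 17827, 16404, 20155 and 7169 in the order above, and no count moved by over 1.5 times. The shift of the chromosome 5 stretch in OE14 was -0.83 with genes of a mean FPKM of 1 or more and -0.81 with 20 or more, and that of the chromosome 18 stretch 0.39 and 0.49. Of 184 values of named genes under an alternative, 181 kept their direction and side of the threshold, 3 became calls and 0 reversed. The 3 were those of Potri.006G234900.v3.0 in OE18 against WT, whose adjusted p ranged from 0.001 to 0.44 over its alternatives; the cause was not tested. The alternatives for the gene lists, the estimated correlation among them, were not run, since the lists could not be applied. Depth limits the genes with few reads: in data simulated for OE14 against WT with genes changed by 1.5-fold, limma called 26 of the 100 with the fewest reads (median 36 per library) and 100 of the 100 with the most (median 756). Few genes were changed in that simulation, so these shares need not hold for the real comparison.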

Other observations

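The test of gene content was chosen only after the results were seen; those of read number and of the length trend were set before theirs were.

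A small set of genes was expressed in WT and had no read in either line. Of 16 genes at a mean of 1 FPKM or more in WT without a read in OE14, 9 also had no read in OE18, where 27 such genes were found. Sets of these sizes drawn independently would share 0.021, but 3 of the 9 lie within 5 listed loci of one another, so the genes are not independent. Their highest WT mean was 10.7 FPKM, and 4 of the 9 lie on chromosome 19. Another 4 genes had no read in OE14 and a mean of 1 FPKM or more in both WT and OE18. They include Potri.T020000.v3.0, the largest fall in OE14, and 2 of the 4 are unplaced loci. The other unplaced locus, close to it in locus number, had a mean of 20.17 FPKM in WT and 46.83 in OE18. A gene of the chromosome 5 stretch is also among the 4, and a different gene of that stretch is among the 9.

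For the 9 genes, too few reads are argued against, because at the WT level each would have at least 111 reads over the 6 libraries of the lines. A sequence or gene content difference between the WT plants and the stock from which the lines were made may account for them, as may repression in both lines. Such a difference might also leave genes without a read in WT that both lines express, and 2 of those were found, too few to decide between the explanations.

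For the extent of the difference between OE18 and WT, the trend with gene length was removed from each library, and 6286 genes were then called at 2-fold or more, against 6422 before, with 5648 in both sets. The length trend is therefore not the whole cause of that difference. High overexpression, the site of the transgene in this line and changes that arose in the line stay open and untested, because OE18 is a single line. A difference between the groups in harvest, library preparation or the drought state of the plants cannot be separated from genotype either. The OE18 libraries had 0.070% to 0.072% of their reads in no listed gene, against 0.048% to 0.049% in WT and 0.049% to 0.051% in OE14. These shares are what the recovered total leaves beyond the reads recovered for listed genes. In data simulated with known reads the recovery missed 0.03% of the reads. Part of each share may therefore be reads of listed genes. The cause of the difference between the groups was not tested.

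The gene with the highest mean FPKM over the 9 libraries, Potri.013G139800.v3.0, was singled out after its values were seen. It was the highest gene in 5 of the 9 libraries. It varied widely within genotypes, with 5424, 11697 and 9922 FPKM in the WT libraries, 8723, 1744 and 4079 in OE14, and 8284, 6804 and 24984 in OE18. It took from 0.148% to 2.12% of the reads of a library.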
